A study of Mus musculus with 4 samples.

How the data were processed

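RNA sequencing was analysed for 4 mouse libraries of a single group. The labels describe satellite cells, the stem cells of skeletal muscle, that derived from transplanted donor cells and were recovered again afterwards. The donor cells came from the iPax3 line, a pluripotent stem cell line from which Pax3-induced myogenic progenitors are made, and carried overexpression of NICD3, the intracellular domain of the Notch3 receptor. The replicate numbers are those of the labels. Cells of the same line without NICD3 are not analysed here, so no comparison between groups was made. Per the labels' protocols, RNA from small numbers of cells was taken up in Buffer RLT and captured on beads. cDNA was made and amplified with a NEBNext kit for single cells or low input, and libraries were built with Nextera XT. Nothing in the labels says that the replicates came from separate animals, so spreads and p-values measure only the differences between these 4 libraries, which may be technical.

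The deposited values are log2 CPM (read counts per 1e+06 reads counted) with a constant offset, per the file headers and the values themselves. The lowest value, the same in all 4 libraries, was -4.19. The submitters' processing notes name Trimmomatic 0.33, FastQC, featureCounts, edgeR and the mouse build mm10, without their order or settings. The aligner, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Near-identical genes, such as Hspa1a and Hspa1b, Ubb, the alpha globins, H3f3b, Eef1a1 and the clustered myosin heavy chains, are therefore uncertain, and so are genes with an overlapping or antisense partner. The table holds 21264 genes.

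From these values, the offset of 0.0548 CPM was removed from 2 raised to each value. The resulting CPM summed to 1e+06 in each library, and 100% of the values were whole multiples of what 1 read is worth, within a tolerance of 1e-06 reads. The depth recovered in this way was 12789849, 13302916, 13063863 and 12544138 reads for replicates 1 to 4, and 1 read was worth between 0.0752 and 0.0797 CPM. A gene without reads may have a level of up to 3 counts, which is between 0.226 and 0.239 CPM. Shares of reads are given with 95% Wilson intervals. Reads amplified from few cells without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The plan had assumed CPM on a linear scale. It was kept, and levels were analysed as recovered CPM and as log2(CPM + 1), which understates differences of genes near or below 1 CPM. No count model was fitted, since there is no second group to compare.

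Gene identifiers were matched to GENCODE M21, which annotates the same assembly as mm10, for coordinates, summed exon length and the GC content of the longest transcript. Of the identifiers, 21224 matched (99.8%) and 40 did not. For 9 symbols on more than 1 row, the row with the higher mean CPM was used. CPM is not corrected for length, so a difference between genes depends on how long they are.

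Gene lists were fixed before the data were examined, 29 in all. They cover satellite cell identity, quiescence, Notch targets, Notch pathway components, myogenic commitment, developmental and adult sarcomere genes, the cell cycle, the dissociation response, extracellular matrix, integrins and cadherins, nuclear oxidative phosphorylation, glycolysis, interferon response, reference genes, Hox genes, paraxial mesoderm, pluripotency and sex-linked genes. The other lists hold markers of fibro-adipogenic progenitors, endothelial, mural, macrophage, neutrophil, lymphocyte, erythroid, glial, tendon and adipocyte cells. Ahsp, Mx1 and Xist of these lists were matched to no row and are not used here. A list's level is the mean log2(CPM + 1) of its members. It was placed among 10000 random lists of as many genes with a mean of 1 CPM or more. The difference between lists, or between paired genes, was taken within each library and tested with an exact two-sided sign-flip permutation test over the 16 sign assignments. The Benjamini-Hochberg adjustment ran over 21 list differences and over 12 gene pairs. The spread of a list between libraries was compared with 10000 random lists of the same size matched on mean level in 25 bins. This gave a one-sided share of random lists at least as wide, adjusted over the 25 lists that could be tested, with 0.05 as the threshold. A gene was called variable when its mean was at least 10 CPM and its SD of log2(CPM + 1) at least 1.

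The genes named are Notch3 and Pax3, the 20 genes with the highest mean CPM apart from mitochondrially encoded and ribosomal protein genes, the 3 most abundant members of each list, the paired genes, and the 10 genes of at least 10 CPM with the largest SD. Some genes that this rule takes are not reported here. Any other gene named was chosen after its values were seen.

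The spread test and the recovery of reads were tested on simulated reads for the real genes at the real depths, for the spread over the 4 libraries. With a dispersion of 0.16, 100% of read counts were recovered. Among 9202 genes with a mean of 10 CPM or more, 56.0% of those raised 4-fold in 1 library and 99.0% of those raised 16-fold reached an SD of 1, as did 3.56% of unchanged genes. A planted list of 20 genes that moved together gave a share of 0.0001, the smallest that 10000 random lists can give, and 2.50% of 200 lists without a planted effect fell under 0.05. The simulated genes varied independently, without a trend in GC content or length. That rate need not hold for real lists whose genes are alike in these.

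Alternatives covered the pseudocount (0.1 and 5), minimum levels, CPM per kb of exon, median-of-ratios scaling, medians in place of means, the choice of random lists and each replicate left out. A lowess correction for transcript length and GC content with a span of 0.3, and the Notch target list without Notch3, were added after the data were seen. Leaving out members that both lists of a difference hold was not part of the plan either. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.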

Results

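The 4 libraries hold RNA of donor-derived satellite cells that carried NICD3 and were re-isolated after transplantation of iPax3 myogenic progenitors. The design text places them in a study of Notch3 gain of function and of its effect on satellite cell engraftment. With 1 group, the data give the level of each gene with its spread (SD, n = 4 throughout), and the differences between gene groups within each library. Depth was 12544138 to 13302916 reads per library. Between 14292 and 14635 genes had reads, and 12469 to 12724 reached 1 CPM in a library. In all 4 libraries 11395 genes reached 1 CPM, and 4816 genes had no read in any library.

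Notch3 and Pax3, the genes of the overexpressed domain and of the inducible line, were both detected in every library. Notch3 (ENSMUSG00000038146, chromosome 17, 32120820 to 32166852, GENCODE M21) stood at 169 ± 15.9 CPM, with values of 168, 191, 162 and 153 CPM in replicates 1 to 4. Pax3 (ENSMUSG00000004872, chromosome 1, 78101267 to 78197134), a transcription factor of muscle progenitors, stood at 45.2 ± 25.9 CPM, with 82.1, 43.5, 31.7 and 23.5 CPM. Reads of a transgene and of the endogenous gene cannot be told apart in these values.

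The Notch target list was led by repressor genes. Heyl, Hes1 and Hey1, transcriptional repressors induced by Notch signalling, reached 896 ± 91.2, 332 ± 76.4 and 271 ± 27.0 CPM. Dtx4, Notch3 and Bhlhe41 followed with means of 238, 169 and 96.1 CPM. Hey2, Nrarp, Lfng, Hes5 and Dtx1 were lower, with means of 27.4, 20.8, 6.73, 6.08 and 0.626 CPM. Of the 11 listed targets, 10 had a mean of 1 CPM or more, and these 10 reached 1 CPM in all 4 libraries. The list mean of 5.76 ± 0.17 (log2 of CPM + 1) lay at the 97.0th percentile of random lists of detected genes. The list holds Notch3 itself, and without it the mean was 5.59 ± 0.20, at the 93.4th percentile. Among Notch pathway components, all 24 had a mean of 1 CPM or more and 23 reached 1 CPM in every library, with a list mean of 5.08 ± 0.13 at the 87.0th percentile. The gamma-secretase subunit Ncstn stood at 381 ± 181 CPM and the ligand Jag1 at 164 ± 94.9 CPM.

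Among the receptors, Notch1 was at 214 ± 23.4 CPM, Notch2 at 25.6 ± 11.4 CPM and Notch4 at 4.58 ± 1.75 CPM. Notch3 lay above Notch2 by 2.81 ± 0.93 and above Notch4 by 4.98 ± 0.38 on the log2 scale in 4 of 4 libraries. It lay below Notch1, with a difference of -0.34 ± 0.10, also in 4 of 4. Each of these differences had an exact sign-flip p of 0.13 (adjusted 0.15). That is the smallest this test can give with 4 libraries, so no difference can pass 0.05 by it. With levels per kb of exon the order of Notch3 and Notch1 turned, to 0.45. Heyl exceeded Hes1 by 1.46 ± 0.30 and Hey1 by 1.72 ± 0.17, each in 4 of 4 libraries. Per kb of exon these differences were 0.13 (exact p = 0.5, n = 4) and 1.07.

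**Figure D1:**
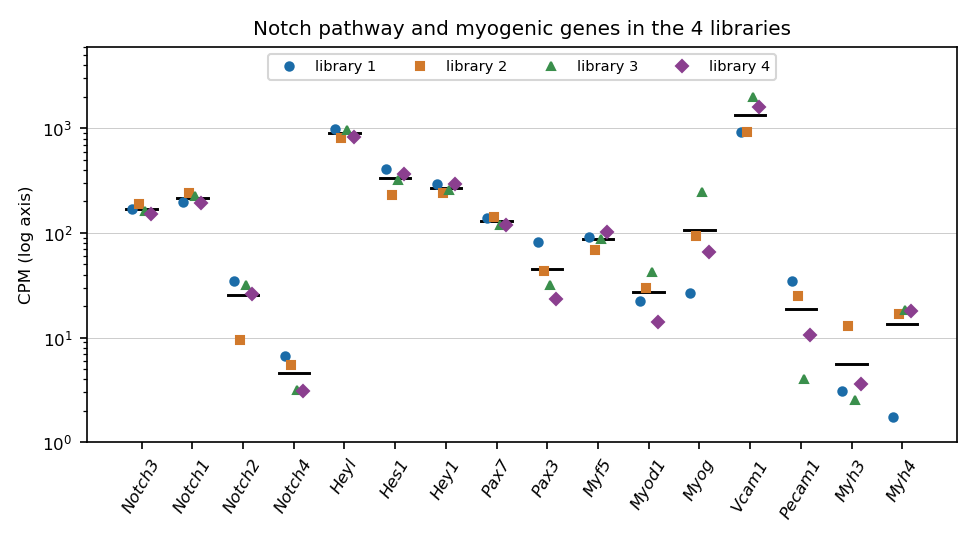
CPM (log axis) of 16 Notch pathway, myogenic and marker genes in the 4 libraries, with each symbol a library and each bar the mean. Notch3, Notch1, Heyl, Hey1 and Pax7 lie close together across libraries, while Myog runs from 26.9 to 245 CPM and Pecam1, an endothelial gene, from 4.06 to 34.7 CPM.

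Genes of the satellite identity list were high as a group, and their mean level varied little between libraries. Pax7, the transcription factor that marks satellite cells (chromosome 4, 139737062 to 139833528), stood at 130 ± 12.4 CPM and Myf5, a myogenic determination factor, at 87.2 ± 13.6 CPM. Dag1 (dystroglycan), the tetraspanin Cd82 and the adhesion molecule Vcam1 reached 2589 ± 266, 1743 ± 473 and 1355 ± 526 CPM. Single members varied more than the mean, with Vcam1 between 914 and 1983 CPM. Pax7 and Myf5 lay below the median of the list, 309 CPM, and Cxcr4 was lowest at 3.07 ± 1.62 CPM. The list mean is thus not the level of Pax7, and it does not measure how pure the cells were. All 20 identity genes reached 1 CPM in every library, and their mean of 8.06 ± 0.08 lay above all 10000 random lists. The same held for the 18 quiescence genes, with a mean of 6.86 ± 0.09. They include the caveolin gene Cav1 at 685 ± 319 CPM and Tgfbr3, a TGF-beta co-receptor, at 473 ± 157 CPM. The quiescence list also holds Heyl, its most abundant member, Hes1 and Hey1, which lead the Notch target list. Its level is therefore not independent of Notch target genes.

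Genes of commitment and differentiation were lower than satellite identity genes, yet present. The 13 commitment genes averaged 4.97 ± 0.51 (73.9th percentile of random lists of detected genes). Taken per library, that percentile had an SD of 28.2. All 13 had 1 CPM or more in each library. Among them Cdkn1a, a cyclin-dependent kinase inhibitor, stood at 224 ± 121 CPM and Myod1 at 27.3 ± 12.2 CPM. Myog (chromosome 1, 134289989 to 134292548), a transcription factor of differentiating myoblasts, was at 108 ± 95.2 CPM. Sarcomere genes of mature fibres averaged 5.35 ± 0.61 (95.8th percentile). Taken per library, that percentile had an SD of 24.3, and the list mean was lowest in replicate 1 at 4.55. Of these genes, 21 of 22 had 1 CPM or more in all libraries. Among them were skeletal actin Acta1 at 781 ± 357 CPM, Actn3 at 540.0 ± 85.2 CPM and titin (Ttn) at 395 ± 216 CPM. The list named developmental sarcomere (15 genes) averaged 3.90 ± 0.55. It is not purely developmental or sarcomeric. It also holds acetylcholine receptor subunits, such as Chrna1 at 281 ± 124 CPM, and slow-fibre genes, such as Myh7 and Tnni1 (87.3 ± 34.6 CPM). The 24 cell cycle genes averaged 3.44 ± 0.39, at the 0.25th percentile of random lists of detected genes and the 86.0th of lists from all genes of the table, led by Pcna at 87.1 ± 29.7 CPM, Mcm7 at 79.2 ± 12.3 CPM and Tyms at 75.2 ± 31.3 CPM.

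Within libraries, satellite identity genes exceeded commitment genes by 3.10 ± 0.45 on the log2 scale, adult sarcomere genes by 2.71 ± 0.59, developmental sarcomere genes by 4.16 ± 0.54 and cell cycle genes by 4.62 ± 0.41. Quiescence genes, which include Heyl, Hes1 and Hey1, exceeded cell cycle genes by 3.41 ± 0.36 and commitment genes by 1.89 ± 0.42 (1.21 per kb of exon). The developmental minus the adult sarcomere list gave -1.45 ± 0.07, with receptor subunits and slow-fibre genes in the first list. Notch targets exceeded commitment genes by 0.79 ± 0.61, by 0.49 without replicate 1, by 0.62 without Notch3, by 1.60 with list medians and by 1.32 over members of at least 1 CPM. All 21 list differences had the same sign in 4 of 4 libraries, with an exact sign-flip p of 0.13 each (adjusted 0.13), again the smallest possible. Pax7 exceeded Pax3 by 1.65 ± 0.66 and Myod1 by 2.31 ± 0.66, and Myod1 minus Myog gave -1.63 ± 0.99, in 4 of 4 libraries each. Per kb of exon, Pax7 minus Myod1 was 0.66 (exact p = 0.25, n = 4). Pax7 minus Myf5 was 0.58 ± 0.34 in 4 of 4 libraries, but -0.88 per kb of exon. Pax7 minus Myog was 0.68 ± 1.38 with that sign in 3 of 4 libraries (exact p = 0.5, n = 4). It was -1.25 per kb, 0.14 without replicate 1 and 1.26 without replicate 3. Myh3 minus Myh4, an embryonic and an adult myosin heavy chain, was -1.06 ± 1.42 in 3 of 4 libraries (exact p = 0.375, adjusted 0.409, n = 4), with -1.61 without replicate 1 and -0.60 without replicate 3.

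**Figure D2:**
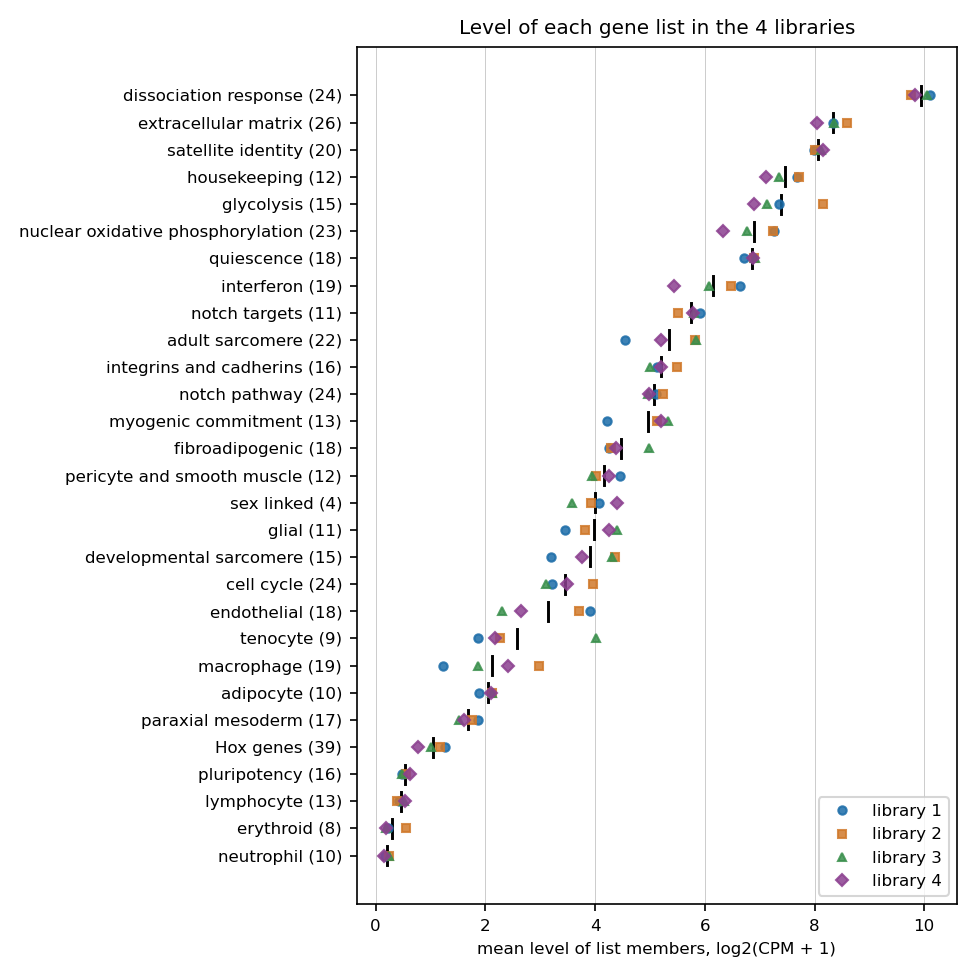
Mean log2(CPM + 1) of the members of each of the 29 gene lists (number of members in brackets) in the 4 libraries, with a bar at the mean. Dissociation response genes lie highest at 9.93, satellite identity genes at 8.06, and neutrophil markers lowest at 0.20.

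As list means, markers of other cell types lay below those of satellite cells. Satellite identity genes exceeded fibro-adipogenic markers by 3.59 ± 0.31, mural markers by 3.90 ± 0.26, glial markers by 4.08 ± 0.36, endothelial markers by 4.92 ± 0.86, tendon markers by 5.48 ± 0.94, macrophage markers by 5.94 ± 0.74 and adipocyte markers by 6.01 ± 0.09, on the log2 scale. For neutrophil, erythroid and lymphocyte markers the differences were 7.86 ± 0.10, 7.77 ± 0.24 and 7.59 ± 0.03. Vcam1 exceeded Pecam1 by 6.39 ± 1.82. The fibro-adipogenic list was led by the collagen gene Col3a1 at 4599 ± 992 CPM, Gsn at 1246 ± 139 CPM and Dpt at 1118 ± 388 CPM, while Pdgfra (0.768 ± 1.04 CPM), a surface marker of these cells chosen here after its values were seen, had 0, 0.376, 2.30 and 0.399 CPM in replicates 1 to 4. Smooth muscle actin Acta2 stood at 590 ± 378 CPM, Rgs5 at 171 ± 85.8 CPM and Pdgfrb at 104 ± 43.7 CPM among mural markers. Acta2 had 1143 CPM in replicate 1, against 287, 483 and 447 CPM in the others. All other mural markers had lower means, from 0.311 CPM (Tagln) to 34.4 CPM (Cspg4). The endothelial genes Eng, Kdr and Tek were at 117 ± 62.0, 27.9 ± 25 and 27.4 ± 5.75 CPM. The macrophage genes Lyz2 and Ctss were at 36.6 ± 22.5 and 11.5 ± 8.77 CPM, and Cd74 had 3.13, 19.5, 13.5 and 68.6 CPM in replicates 1 to 4, so its mean rests on replicate 4. Among adipocyte markers Car3, which muscle also expresses, reached 686 ± 402 CPM, Lpl 25.1 ± 12.4 CPM and Lipe 17.2 ± 7.48 CPM. Lck (4.02 ± 2.21 CPM) and Cd3e (2.40 ± 0.654 CPM) led the lymphocyte markers, Alas2 (1.65 ± 0.978 CPM) the erythroid and Ltf (0.944 ± 0.682 CPM) the neutrophil markers.

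Pluripotency genes averaged 0.53 ± 0.07, and satellite identity genes exceeded them by 7.53 ± 0.08 (4.35 over members of at least 1 CPM). Klf2, which many cell types express, made up most of it with 77.6 ± 10.4 CPM, and Tfcp2l1 followed with 1.49 ± 1.28 CPM. Pou5f1 and Sox2, core pluripotency factors chosen here after their values were seen, had no read in any library, which allows up to 0.226 to 0.239 CPM per library.

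The most abundant transcripts included chaperone, immediate early and matrix genes. The endoplasmic reticulum chaperone Hspa5 led with 9357 ± 1449 CPM, followed by the polyubiquitin gene Ubb (8825 ± 5106 CPM), Dnajb1 (7624 ± 1805 CPM), Igfbp5 (6101 ± 1821 CPM) and Hspa8 (5826 ± 1682 CPM). Fos, Egr1, Btg2, Dusp1, Jun, Junb and Ier2, immediate early genes, were also among the top 20, with Fos at 5727 ± 1784 CPM and Egr1 at 5251 ± 1227 CPM. The 24 genes of the dissociation response, those known to be induced when tissue is dissociated, took 5.37 ± 1.07% of all reads. Their mean of 9.93 ± 0.17 exceeded that of reference genes (7.47 ± 0.28, led by Eef1a1 at 2489 ± 1234 CPM and Actb at 2001 ± 512 CPM) by 2.47 ± 0.31 in 4 of 4 libraries.

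Matrix genes averaged 8.33 ± 0.23, with all 26 at 1 CPM or more in each library. The proteoglycan Bgn stood at 2700 ± 765 CPM and Sparc at 2356 ± 798 CPM. Integrins and cadherins averaged 5.21 ± 0.21, with Cdh13 at 1206 ± 656 CPM, Itgb1 at 804 ± 347 CPM and Cdh15, M-cadherin, at 599 ± 132 CPM. Glycolysis genes averaged 7.38 ± 0.54, led by Pkm at 1325 ± 758 CPM and Aldoa at 1010 ± 528 CPM, and nuclear oxidative phosphorylation genes 6.90 ± 0.45, led by Atp5b at 764 ± 233 CPM and Uqcrc1 at 758 ± 364 CPM. Oxidative phosphorylation minus glycolysis was -0.48 ± 0.35 in 4 of 4 libraries, 0.42 with levels per kb of exon and -0.04 with list medians. Interferon response genes averaged 6.16 ± 0.53, with H2-D1, a class I histocompatibility gene, at 712 ± 200 CPM, Ifitm3 at 563 ± 302 CPM and B2m at 288 ± 85.7 CPM.

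Across 12879 genes, the Pearson correlation of log2(CPM + 1) between pairs of libraries ran from 0.862 (replicates 1 and 4) to 0.906 (1 and 2), and Spearman's from 0.865 to 0.910. These are correlations across genes, which are not independent replicates. Chi-square values per degree of freedom of 114 to 233 show that no pair held the same library. The median SD of a gene with 10 CPM or more was 0.62 on the log2 scale, and 191 of 9202 such genes (2.08%) had an SD of 1 or more. In the simulation with a dispersion of 0.16, 3.56% of unchanged genes reached that SD. That dispersion is near the spread of these same libraries, whose genes between 30 and 100 CPM had a median CV beyond counting error of 41.3%. The simulated noise thus already holds the spread between these libraries. The comparison cannot say whether the observed share is large. The count of 191 depends on the minimum level, with 765 genes at a minimum of 1 CPM and 31 at 50 CPM. The count was 510, 789, 737 and 431 genes when replicate 1, 2, 3 or 4 was left out. There the SD rests on 3 libraries, so this rise cannot be read as a dependence on particular libraries.

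Several gene groups moved together between libraries. Of 25 lists, 12 spread more than matched random lists, 8 of them with a share of 0.0001, the smallest that 10000 random lists can give. Adult sarcomere genes were lowest in replicate 1 at 4.55, against 5.82, 5.83 and 5.20 in the others, and none of the 21 detected members was highest there (adjusted share 0.000313). Developmental sarcomere genes (3.19 in replicate 1, against 4.36, 4.31 and 3.75; 0.000313) and commitment genes (4.22, against 5.12, 5.33 and 5.20; 0.00167) were also lowest in replicate 1. Without replicate 1 their adjusted shares were 0.0919 and 0.799. Endothelial markers were higher in replicates 1 and 2 (3.90 and 3.71) than in 3 and 4 (2.30 and 2.65), and macrophage markers were highest in replicate 2 (2.98), with 13 of 15 detected members, but not Cd74, at their maximum there. Tendon markers were highest in replicate 3 (4.02, against 1.86, 2.26 and 2.18), and without replicate 3 their adjusted share was 0.449. Glial markers ran from 3.45 in replicate 1 to 4.40 in replicate 3 (0.0215), with 0.191 without replicate 1 and 0.0698 without replicate 3. The tendon genes Fmod and Thbs4 had 163 and 61.8 CPM in replicate 3. Chodl, the most abundant gene of that list, was at 321 ± 82.3 CPM over all 4, from 241 to 433 CPM.

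**Figure D3:**
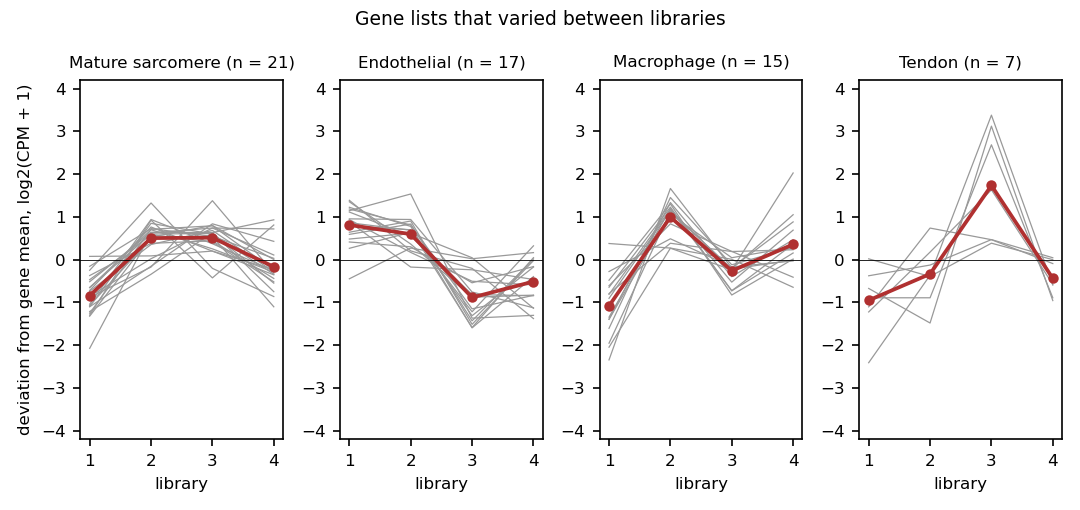
Deviation of log2(CPM + 1) from each gene's own mean in the 4 libraries, for members with a mean of 1 CPM or more of 4 lists. Grey lines are genes and the red line is their mean; libraries have no order. Adult sarcomere genes are lowest in library 1, endothelial genes higher in 1 and 2, macrophage genes highest in 2 and tendon genes highest in 3.

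Glycolysis genes were highest in replicate 2 (8.15, 14 of 15 members) and cell cycle genes as well (3.96, 14 of 24), with adjusted shares of 0.000313 and 0.002. Without replicate 2 these were 0.290 and 0.318. Interferon response genes ran from 6.64 in replicate 1 to 5.44 in replicate 4 and oxidative phosphorylation genes from 7.26 to 6.33, both with an adjusted share of 0.000313. Hox genes (1.27 in replicate 1, 0.77 in replicate 4) had an adjusted share of 0.0182, which was 0.0736 without replicate 1, 0.290 without replicate 4 and 0.352 after the correction for transcript length and GC content. Satellite identity (0.789), quiescence (0.783), Notch target (0.733) and Notch pathway genes (0.606) did not spread more than matched lists. Nor did mural (0.413), adipocyte (0.623), fibro-adipogenic (0.0612), matrix (0.0542), integrin and cadherin (0.293), dissociation response (0.286), reference (0.124), paraxial mesoderm (0.375) and sex-linked genes (0.294). The matrix list passed without replicate 1 (0.0164) or 3 (0.0455) and with a pseudocount of 5 (0.0285), and the fibro-adipogenic list without replicate 4 (0.0255).

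Library composition also differed. Mitochondrially encoded genes took 0.533% (95% Wilson interval 0.529 to 0.537), 0.981% (0.975 to 0.986), 0.822% (0.817 to 0.827) and 1.82% (1.81 to 1.82) of reads in replicates 1 to 4. Ribosomal protein genes took 1.66% (1.65 to 1.67), 1.34% (1.33 to 1.35), 0.855% (0.850 to 0.860) and 0.641% (0.637 to 0.646). Across 9195 genes of 10 CPM or more, the deviation of a library from the gene mean correlated with transcript GC content with a Spearman coefficient of 0.435 in replicate 1, 0.219 in 2, 0.0061 in 3 and -0.555 in 4.

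**Figure D4:**
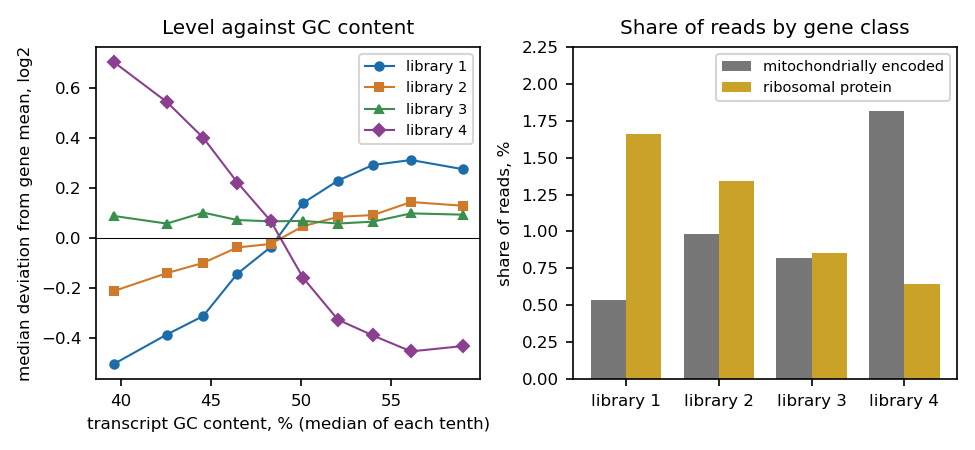
Left, median deviation of log2(CPM + 1) from the gene mean against transcript GC content (%), for genes of 10 CPM or more in 10 bins of equal size, 1 line per library. Right, share of reads (%) taken by mitochondrially encoded and ribosomal protein genes in each library. Replicates 1 and 4 have opposite GC trends, and replicate 4 has the highest mitochondrial share (1.82%) and the lowest ribosomal protein share (0.641%).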

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

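Each named gene, list, difference and library measure was searched for a library that lies apart from the other 3 by Dixon's criterion. Of 190 measures 14 stood out, where chance alone gives about 9.5. The test of length and GC content as the whole cause of the first pattern and the stricter counts of tendon genes were chosen only after the result was seen; the other tests below were set beforehand, on patterns already noticed in the data.

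In replicate 1, Myh7, the slow myosin heavy chain, had 6.41 CPM against 98.5, 71.7 and 67.8 CPM, and Myh4, a fast one, 1.72 CPM against 16.7, 18.1 and 17.9 CPM. Notch targets minus commitment genes was 1.70 in replicate 1 against 0.39, 0.47 and 0.59, and adipocyte markers were 1.89 there against 2.12, 2.12 and 2.11. In replicate 2, Gsn had 1453 CPM against 1177, 1199 and 1155 CPM, and Notch3 minus Notch2 was 4.19 against 2.24, 2.31 and 2.50. Klf1 had 2.93 CPM and erythroid markers a mean of 0.56 in replicate 2, the others lying at 0.23 or lower for the list. In replicate 3, Ngp had 3.21 CPM with at most 0.0797 CPM elsewhere, Klrb1c had 0 CPM against 1.02 to 1.28 CPM, and satellite identity minus fibro-adipogenic markers was 3.13 against 3.71 to 3.78. In replicate 4, Hoxc10 had 0 CPM against 33.9 to 48.5 CPM, Prdm14 had 1.28 CPM with no read elsewhere, and Hba-a2 had 0.717 CPM with at most 0.0782 CPM elsewhere.

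Nuclear oxidative phosphorylation and ribosomal protein genes were lower in replicate 4 than in replicate 1 in 88 of 96 genes, with a median difference of -1.41 on the log2 scale, while 9 of 9 mitochondrially encoded genes were higher in replicate 4 by a median of 1.83. The tables argue against a few genes taking most of the counts, since median-of-ratios scaling left 99.5% of the median and the median over all genes differed by -0.0089. After a correction for transcript length and GC content, 87 of 96 genes were still lower in replicate 4, with a median of -0.89 (interquartile range -1.28 to -0.55). That cannot exclude length and GC content together as the whole cause. Summed exon length and the GC content of the longest transcript need not be those of the transcripts expressed. How large a part length and GC content have stays open, because the 63.6% left lies between the bounds of 50 and 80 set beforehand, and the difference between these libraries correlated with GC content (Spearman -0.555 across genes) and with exon length (0.268), while the pattern's genes were near all genes in GC content (median 49.5% against 49.2%) and shorter (2011 against 4794 bases). No biological explanation was tested, since both libraries belong to 1 group.

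A set of 31 genes with a mean of 10 CPM or more had no read in at least 1 library, although their highest library held 214 to 1424 reads. Sampling of reads from a level shared by all 4 libraries is argued against by these read counts, which say nothing about where the difference arose. Few starting molecules per gene before amplification, a candidate explanation, cannot be told apart from other sources, since the slope of the extra-Poisson squared CV on mean level was -0.417 ± 0.0374 (SE), between the bounds of -0.5 and -0.2 set beforehand. The slope was -0.553 from 1 to 10 CPM and -0.157 from 10 to 100 CPM. No biological explanation was tested.

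Tendon markers were highest in replicate 3, in 6 of 7 detected genes. Of these 6, Tnmd had reads only in replicate 3 (10.9 CPM) and counts as detected through that library alone. Chodl, also among the 6, was high in every library (241 to 433 CPM). In replicate 3, 9 of 16 detected fibro-adipogenic markers were highest as well, a list whose spread did not pass (adjusted share 0.0612). Of a second list of tendon and connective tissue genes, none of them on another list, 10 of 19 detected genes were also highest there, with 2, 4 and 3 in replicates 1, 2 and 4 (exact one-sided binomial p = 0.0089 against 1 in 4). RNA of tendon or connective tissue cells in replicate 3 and independent loss of molecules cannot be told apart by this, although the p lies under the 0.05 set beforehand, since genes are not independent and the count fell to 7 of 16 (exact p = 0.0796) among genes with a mean of 1 CPM or more without their highest library and to 4 of 11 (exact p = 0.287) at a mean of 10 CPM or more. Dcn was highest there (52.8 CPM, against 9.15, 2.93 and 15.4 CPM), Col1a1, abundant in tendon, was not (657 CPM, against 642, 966 and 385 CPM), and Col12a1 (103 CPM), Cilp (66.1 CPM) and Omd (0.0765 CPM) were lowest there, all chosen after their values were seen. Expression of these genes by the donor-derived cells themselves stays open and was not tested.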

How the results depend on the processing

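Most alternatives were set before the data were examined. The length and GC correction, the stricter levels for the second tendon list and the Notch target list without Notch3 were not. Leaving out members that both lists of a difference hold was not planned either. Of the alternatives to the 21 list differences, 209 kept their direction and 1 turned; of those to the 12 gene pairs, 93 kept it and 3 turned. All 4 turned with CPM per kb of exon, to 0.42 for oxidative phosphorylation minus glycolysis, 0.45 for Notch3 minus Notch1, -0.88 for Pax7 minus Myf5 and -1.25 for Pax7 minus Myog, since exon lengths differ. No difference can pass 0.05 in the sign-flip test with 4 libraries, so its p says nothing about stability. The count of variable genes (191) was 765 and 31 with minimum levels of 1 and 50 CPM, 328 and 57 with pseudocounts of 0.1 and 5, and 431 to 789 with a replicate left out, where the SD rests on 3 libraries. The median Pearson correlation (0.896) was 0.958 with no minimum level, 0.835 with a minimum of 10 CPM and 0.854 with a pseudocount of 0.1; the cause was not tested. Of the 12 lists with a wide spread, 8, 10, 10 and 11 passed without replicates 1 to 4, and 11 after the length and GC correction. Glial markers also missed the threshold with a pseudocount of 0.1. With random lists from all genes of the table, 17 of 29 list percentiles moved by more than their SD over the libraries, since that pool holds undetected genes. By this rule the neutrophil list, with an SD of 0, counted as moved at 0.01. Commitment genes, with an SD of 28.2, could shift far and still count as unmoved. The number of detected genes stayed within 1.5 times. Leaving out 1 replicate moved the mean of 19 of the 120 genes taken by the rule by over 1.5 times, such as Fmod (46.3 to 7.52 CPM) and Myog (108 to 62.2 CPM) without replicate 3, and Cd74 without replicate 4. Leaving out members that both lists of a difference hold gave no value, since no such pair shares a member. Neutrophil, lymphocyte, erythroid and pluripotency lists had too few detected members for the spread test. Depth limits genes below about 0.239 CPM.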

Other observations

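Neural crest and glial genes were among the transcripts outside the myogenic lists. Pmp22, a myelin protein gene that other cells also express, stood at 428 ± 201 CPM and the neurotrophin receptor gene Ngfr at 152 ± 64.2 CPM. Sox10, a transcription factor of neural crest and glia chosen here after its values were seen, stood at 118 ± 23.3 CPM, with 112, 111, 151 and 97.1 CPM in replicates 1 to 4. The glial list of 11 genes averaged 3.98 ± 0.43, at the 16.3rd percentile of random lists of detected genes (SD 15.3 over libraries). Among lists from all genes of the table it lay at the 91.2nd.

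The paraxial mesoderm list averaged 1.69 ± 0.16, with 9 of 17 genes at a mean of 1 CPM or more, led by the somite factor Dmrt2 at 106 ± 19.4 CPM, Pax3 at 45.2 ± 25.9 CPM and Meox1 at 12.7 ± 2.59 CPM. Hox genes averaged 1.05 ± 0.22, with 15 of 39 at a mean of 1 CPM or more, led by Hoxc10 at 32.4 ± 22.6 CPM, Hoxc8 at 14.8 ± 8.82 CPM and Hoxb7 at 11.3 ± 4.66 CPM. The sex-linked list, here 4 Y-linked genes, averaged 3.99 ± 0.34. The Y-linked genes Ddx3y, Eif2s3y and Uty stood at 97.3 ± 26.7, 51.2 ± 19.6 and 13.1 ± 4.69 CPM, while Kdm5d, a further Y-linked gene chosen after its values were seen, had no read in any library.

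The 10 genes with the largest spread among those of 10 CPM or more were present in some libraries and missing, or nearly so, in others. Kbtbd8 had 48.2 and 80.8 CPM in replicates 3 and 4 and no read in 1 and 2. Kcna5, a potassium channel gene, had 62.2 and 64.9 CPM in replicates 1 and 4 and no read in 2 and 3. Cytl1 had 37.4 and 95.3 CPM in replicates 2 and 4 and no read in the others, and Tcf24 and Gimap5 had reads in the same libraries only. Ush1c had 106 CPM in replicate 3, Gjb1 37.4 and 21.1 CPM in replicates 3 and 4, Syt5 no read in replicate 4 and 109 CPM in replicate 3, and Zfp791 21.6 and 35.7 CPM in replicates 2 and 4. Gad1, which encodes a glutamate decarboxylase, had 0.0782, 27.1, 87.7 and 135 CPM in replicates 1 to 4.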
